A study of Mus musculus with 7 samples.

How the data were processed

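The measurement was chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against the vitamin D receptor (VDR), in epithelial cells shed with EDTA from the proximal small intestine (duodenum and jejunum) of wild-type mice. Per the labels, mice aged 8 weeks received 1,25(OH)2D3, the hormonal form of vitamin D, at 10 ng per g body weight, or vehicle, and tissue was taken 1 h later. The 6 libraries with a peak list were grouped by the treatment in their titles, 3 vehicle and 3 1,25(OH)2D3. A single input library has no file of its own and entered no test. Its label gives the 1,25(OH)2D3 dose of 10 ng per g, and no input from vehicle mice is listed. The labels do not say whether each library came from its own mouse, so p values describe the spread between these libraries only. The labels name a GAIIx and a HiSeq2000 sequencer without saying which libraries ran on which.

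The authors aligned reads to mm9 with Bowtie and called peaks with HOMER, without giving versions. Per the file headers, each library was called alone in factor mode against 1 shared input, at a false discovery rate of 0.001. The headers also give at least 4-fold more tags than in the input and than in the surrounding 10 kb, a Poisson p limit of 0.0001, and a clonal filter of 2. The files hold the deposited start and end of each peak in bases, with a width fixed per library. The deposited score column holds 1 for every peak and so ranks nothing. Tag counts per peak are not given, so the comparisons rest on the presence or absence of peaks.

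The score was to rank the peaks, with peak width in its place if there was none, but both are constant within a library. The order of the list was used in their place, a choice made after the files were seen. It follows the peak numbers within each chromosome, with Spearman correlations from 0.821 to 0.995. What HOMER value it follows is not stated, so a list percentile below is a position in the list (100 for the first peak) and not a measured occupancy.

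Peaks on chromosomes 1 to 19, X and Y were merged across the 6 libraries wherever they overlapped by at least 1 bp. Genes came from GENCODE mouse version 1 (Ensembl 65), on build NCBI 37, which is mm9, and 0 peaks ran past a chromosome end. A later RefSeq table on another build was not used. The gene given as nearest to a region is the protein-coding gene whose outermost annotated start is closest to the region's centre. Location was assigned at the peak centre, in the order within 1 kb of a transcription start, exon, intron and between genes, and compared with 100000 random positions. The VDR element, a direct repeat with a 3 bp spacer (DR3), was searched as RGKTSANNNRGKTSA within 100 bp of each centre on both strands with at most 2 mismatches. The stricter setting allowed 1 mismatch. The background was the windows 5 kb to the right, and 14 other motifs were searched in the same way.

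A total of 15 gene lists were fixed before the files were seen. They are calcium transport; vitamin D metabolism and receptor; phosphate, zinc, iron, magnesium and manganese transport; bile acid and xenobiotic handling; enterocyte function; intestinal transcription factors; stem cell and Wnt; goblet cell; Paneth cell; enteroendocrine and tuft cell; immune cell; stromal, endothelial and muscle cell; neuronal; tight junction and cell adhesion; and cell cycle and growth control. Of 187 symbols, 184 were found, and Slc51a, Slc51b and Pla2g2a were not (the first pair is present as Osta and Ostb). For each list, the share of genes with a region in at least 2 of 3 1,25(OH)2D3 libraries within 50 kb of the gene body was compared with 10000 random lists of the same size. Random lists were matched in 10 strata of gene length and 10 of distance to neighbouring genes, among 22225 protein-coding genes. Tests were one-sided, with Benjamini-Hochberg adjustment over the 15 lists and a threshold of 0.05. The files hold no expression values, so the random genes are not restricted to genes active in the intestine.

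Group differences in single values per library were tested by exact two-sided permutation of the group labels, for which 3 against 3 gives a smallest p of 0.1. Shares of regions carry 95% Wilson intervals, which cover counting error only. The tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined, apart from those listed here and in the closing section as added. The rule named the 10 regions highest in the lists among those in all 3 1,25(OH)2D3 and no vehicle library, the 10 highest among those in all 6, and the 5 highest in all 3 vehicle libraries only. It also took the members of the calcium and vitamin D lists, and up to 4 members of every other list with the most libraries holding a peak. Ties in the last step were broken by the number of regions in at least 2 of 3 1,25(OH)2D3 libraries and then by name, a rule set after the values were seen. The values of 3 genes that the rule named are not reported here.

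Other settings fixed in advance were other overlap rules, other windows and mismatch numbers, all contigs, crowded regions left out, presence in at least 2 of 3 libraries, a replicate block (for peak number, overlap and motif) and leaving out each library (for peak number, overlap and region counts). Added after the data were seen were equal-length lists (the first 8755 peaks of each) and the first 50% of each list, both by list order. Also added were the 4 shallow libraries (those under 20000000 tags) alone, gene-list settings with treated-only regions, with the number of regions per gene and with 1 gene per cluster of neighbours, leave-one-out versions of the location, motif and gene-list results, and the replicate block for location. The pipeline was tested on simulated data, where it found 100% of planted regions and motifs, gave an unadjusted p under the threshold for 2% of 200 random lists, and called 5 of 5 planted lists. The planted sites were well apart and the planted motifs exact, so their recovery checks the code only. Simulated regions for the lists were uniform over the genome, unlike real peaks, so 2% need not be the error rate here. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9.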

Results

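Occupancy of the genome by the vitamin D receptor was mapped in proximal small-intestinal epithelium of mice given vehicle (3 libraries) or 1,25(OH)2D3 (3 libraries) for 1 h. The vehicle libraries held 19733260, 15991198 and 68560701 tags (replicates 1, 2 and 3), and the 1,25(OH)2D3 libraries 17152461, 17438643 and 66524392, so replicate 3 was the deep library of each group. Peaks of the 6 libraries merged into 87029 regions, of which 54468 (62.6%) were found in 1 library only. The series asks, by its title, which target genes the hormone-bound receptor controls in this tissue and whether calcium-regulating genes are among them.

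After 1,25(OH)2D3, a larger share of the tags lay in VDR peaks. The share was 15.6% ± 3.56 (SD, n = 3) with hormone and 5.16% ± 2.78 (SD, n = 3) with vehicle, a difference of 10.4 percentage points (exact permutation p = 0.1, the smallest 3 against 3 can give). All 3 1,25(OH)2D3 libraries were above all 3 vehicle libraries. The estimated fragment length separated the groups as well, at 254, 260 and 280 bp with vehicle and 284, 288 and 282 bp with hormone (exact permutation p = 0.1). The input comparison removed 68.1% ± 8.37 of putative peaks with vehicle and 52.4% ± 9.98 with hormone (SD, n = 3, exact permutation p = 0.2). The only input in the labels carries the 1,25(OH)2D3 dose, so this step may not be matched to treatment in the vehicle libraries. The order of the tag shares held among the 4 shallow libraries, those of replicates 1 and 2 (13.9% against 3.70%) and between the deep libraries (18.96% against 8.10%). The interval from tag counting was narrow, for example 2.58% to 2.59% in vehicle replicate 1 (95% Wilson).

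The number of peaks did not separate the groups. It was 32540 ± 8317 (SD, n = 3) with hormone and 24022 ± 21354 (SD, n = 3) with vehicle, a difference of 0.79 on the log2 scale (exact permutation p = 0.4). The shallow libraries held 27949.5 peaks on average with hormone and 11821 with vehicle, while the deep pair was reversed, at 41721 and 48424. The log2 difference was 1.48 without vehicle replicate 3 and 0.25 without vehicle replicate 1. Vehicle replicate 3 stood apart in its list, since 32166 of its regions (66.4%) were found in no other library, compared with 12736 (30.5%) in 1,25(OH)2D3 replicate 3.

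**Figure D1:**
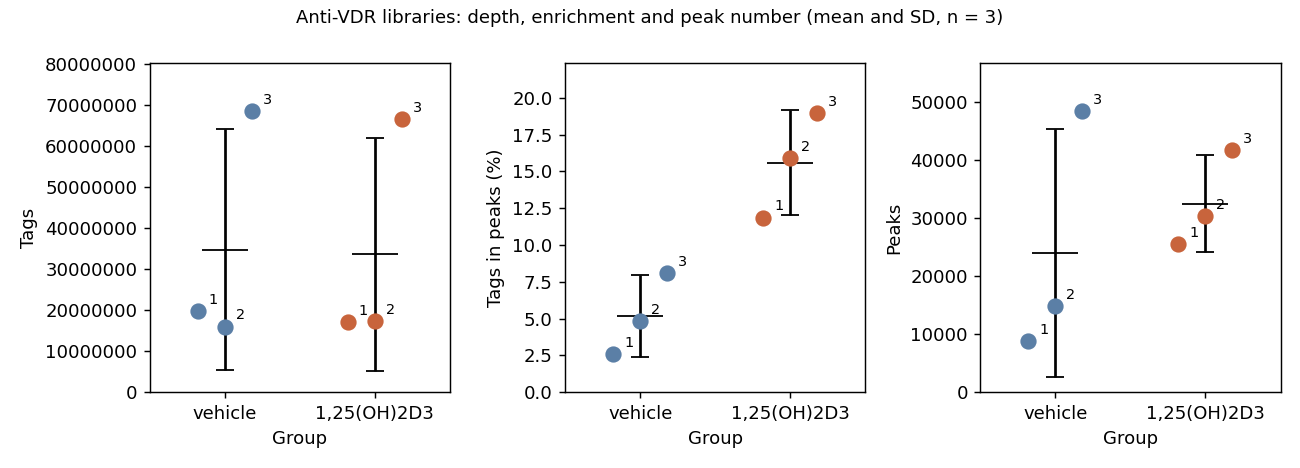
Tags, percent of tags in peaks and number of peaks for each anti-VDR library, by group. Points are libraries with their replicate numbers, and bars show the mean and SD (n = 3). The share of tags in peaks is at least 11.86% in every 1,25(OH)2D3 library and at most 8.10% in every vehicle library.

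Many VDR regions were present in every hormone-treated library and absent from every vehicle library, while the opposite was rare. There were 4687 regions in all 3 1,25(OH)2D3 libraries and no vehicle library (hormone-only below), and 26 in all 3 vehicle libraries and no 1,25(OH)2D3 library (vehicle-only). A further 4345 regions were in all 6 libraries. Of the 4640 regions in all 3 vehicle libraries, 93.6% (95% Wilson interval 92.9 to 94.3) were also in all 3 1,25(OH)2D3 libraries. Of the 17875 regions in all 3 1,25(OH)2D3 libraries, 73.8% had a peak in at least 1 vehicle library and 24.3% in all 3.

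The hormone-only regions were mostly from the middle of the lists, with a median list percentile of 51.0 (interquartile range 31.9 to 68.9), against 89.1 for regions in all 6 libraries. Among the shallow libraries 8600 regions were in both 1,25(OH)2D3 and neither vehicle library, and 206 the other way round. Between the deep libraries alone, 27063 regions were only with hormone and 33766 only with vehicle. The hormone-only count was 7563 without vehicle replicate 3 and 8297 without 1,25(OH)2D3 replicate 1, and 762 with lists of equal length. The vehicle-only count was 220, 104 and 142 without vehicle replicates 1, 2 and 3, 43 and 56 without 1,25(OH)2D3 replicates 2 and 3, and 177 with lists of equal length. The count in all 6 was 6935 when vehicle replicate 1 was left out and 2804 with lists of equal length.

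The hormone-only region placed highest in the lists lay 31.8 kb downstream of the start of Slc30a10 (ENSMUSG00000026614.6), which encodes a manganese exporter. It spanned chromosome 1 positions 187310333 to 187310622 (mm9), between genes, at a mean list percentile of 99.2, and held a DR3 element with 0 mismatches. The next were in introns of Mob1b (chromosome 5, 89153268 to 89153567), a Hippo pathway adaptor, and of Mgat5 (chromosome 1, 129103691 to 129104007), which branches N-linked glycans. A region within Ptprj, a receptor tyrosine phosphatase, on chromosome 2 (90319725 to 90320050) also held a DR3 with 0 mismatches. Hormone-only regions with centres close to transcription starts, the distance being negative upstream, were found at Timm17a, a subunit of the mitochondrial import machinery (at -157 bp; chromosome 1, 137210358 to 137210665), at Elmod2 (at -188 bp; chromosome 8, 85856423 to 85856722) and at Parp16, an ADP-ribosyltransferase of the endoplasmic reticulum (at 93 bp; chromosome 9, 65062434 to 65062746). A region on chromosome 10 (79605223 to 79605523) lay within Atp5d, a subunit of the mitochondrial ATP synthase, close to one of its annotated transcription starts and 1.79 kb upstream of the start of Dos. The remaining members of the first 10 had Gm826 (chromosome 2, 160075491 to 160075842) and Prkar2a, a regulatory subunit of protein kinase A (chromosome 9, 108592372 to 108592684), as the nearest gene start. Their mean list percentiles went from 95.7 to 97.6 outside the Slc30a10 region.

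Slc30a10 also had the region placed highest among those in all 6 libraries, 47.9 kb downstream of its start (chromosome 1, 187326482 to 187326788). It was followed by a region 321 kb upstream of Atp2b1, the basolateral calcium pump (chromosome 10, 98056588 to 98056894). The promoter of Cyp24a1, which encodes the enzyme that inactivates the hormone, held a region centred at -253 bp from its start in all 6 libraries (chromosome 2, 170322730 to 170323066), which also lies within the overlapping gene Pfdn4. Others were at the starts of Muted (chromosome 13, 38726856 to 38727149), Agpat1, an enzyme of phospholipid synthesis (chromosome 17, 34741103 to 34741401), and Ppox, an enzyme of haem synthesis (chromosome 1, 173211117 to 173211426). An intron of Slc37a2, a sugar-phosphate carrier, held another (chromosome 9, 37053913 to 37054214). Others lay 137 kb upstream of Rbbp8 (chromosome 18, 11654981 to 11655284) and 512 kb from Med13l (chromosome 5, 119522825 to 119523212). The mean percentile of each of these regions was at least 99.9.

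Among the 26 vehicle-only regions, the first stood at a mean percentile of 93.2 in the vehicle lists. This is the highest of far fewer regions than in the other classes, so it does not rank the classes. The first vehicle-only region was at the start of Slc33a1, an acetyl-CoA transporter (chromosome 3, 63768511 to 63768812), and the next 4 were nearest to Mgst2 (chromosome 3, 51475136 to 51475442), Hist1h4c (chromosome 13, 23790202 to 23790583), Timm10 (chromosome 2, 84666909 to 84667241) and Apoh (chromosome 11, 108168442 to 108168753, in an intron of Prkca). None of the 5 held a DR3 element with fewer than 2 mismatches. The same was true of the hormone-only regions named above at Mob1b, Mgat5, Prkar2a, Elmod2 and Parp16. Those at Timm17a, Gm826 and Dos held one with 1 mismatch, and those at Slc30a10 and Ptprj one with 0.

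Trpv6, S100g and Atp2b1 of the calcium list and Cyp24a1 of the vitamin D list each had regions present in all 6 libraries and hormone-only regions. Over all protein-coding genes, the mean number of regions within 50 kb was 2.83 for regions in at least 2 of 3 1,25(OH)2D3 libraries and 1.05 for those in at least 2 of 3 vehicle libraries. Trpv6, the apical calcium channel, had 3.33 ± 1.53 peaks per library within 50 kb with hormone and 1.33 ± 0.58 with vehicle (SD, n = 3). A region 1.93 kb upstream of its start (chromosome 6, 41588158 to 41588512) was in all 6 libraries, and one 3.97 kb upstream (41590204 to 41590548) was in all 3 1,25(OH)2D3 libraries only. Both held a DR3 element with 1 mismatch. S100g, which encodes the cytosolic calcium carrier calbindin-D9k, had 5 peaks in each 1,25(OH)2D3 library and 2.33 ± 0.58 with vehicle. Its regions 2.98 kb (chromosome X, 159405335 to 159405678) and 22.7 kb upstream (159425033 to 159425353) were in all 6 libraries, the latter with a DR3 of 0 mismatches. The region 5.61 kb upstream (159407957 to 159408317) was hormone-only. The closest DR3 had 3 mismatches in the region at 2.98 kb and 2 in that at 5.61 kb. All 3 regions lie in introns of the neighbouring gene Ctps2. Atp2b1 had 11.3 ± 5.13 peaks with hormone and 4.33 ± 3.21 with vehicle, and a hormone-only region at -296 bp from its start (chromosome 10, 98377334 to 98377646).

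Cyp24a1 had 9.33 ± 0.58 peaks per library with hormone and 6.33 ± 3.21 with vehicle (SD, n = 3). Besides its promoter, regions 35.3, 37.1 and 42.8 kb downstream of its start were in all 6 libraries, each with a DR3 of 1 mismatch, and regions 20.5 kb downstream and 11.1 kb upstream were hormone-only. The closest DR3 had 2 mismatches at the promoter, 3 in the region at 20.5 kb and 2 in that at 11.1 kb. A region at 39.4 kb (chromosome 2, 170283116 to 170283404) was in 2 of 3 1,25(OH)2D3 libraries at a mean percentile of 99.7 and in no vehicle library. Vdr itself had 9.33 ± 0.58 and 6.67 ± 2.31 peaks with hormone and vehicle, including regions in all 6 libraries in an intron 6.96 kb downstream of its start and 19.2 kb upstream. Slc8a1, Cldn12, Cyp2r1 and Casr had 0 peaks in vehicle replicates 1 and 2 and 4, 2, 3 and 5 in vehicle replicate 3, against means of 0, 0.333, 0.333 and 1.67 with hormone. Gc had 2, 3 and 6 with vehicle and 2.67 on average with hormone. No test was run for single genes.

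**Figure D2:**
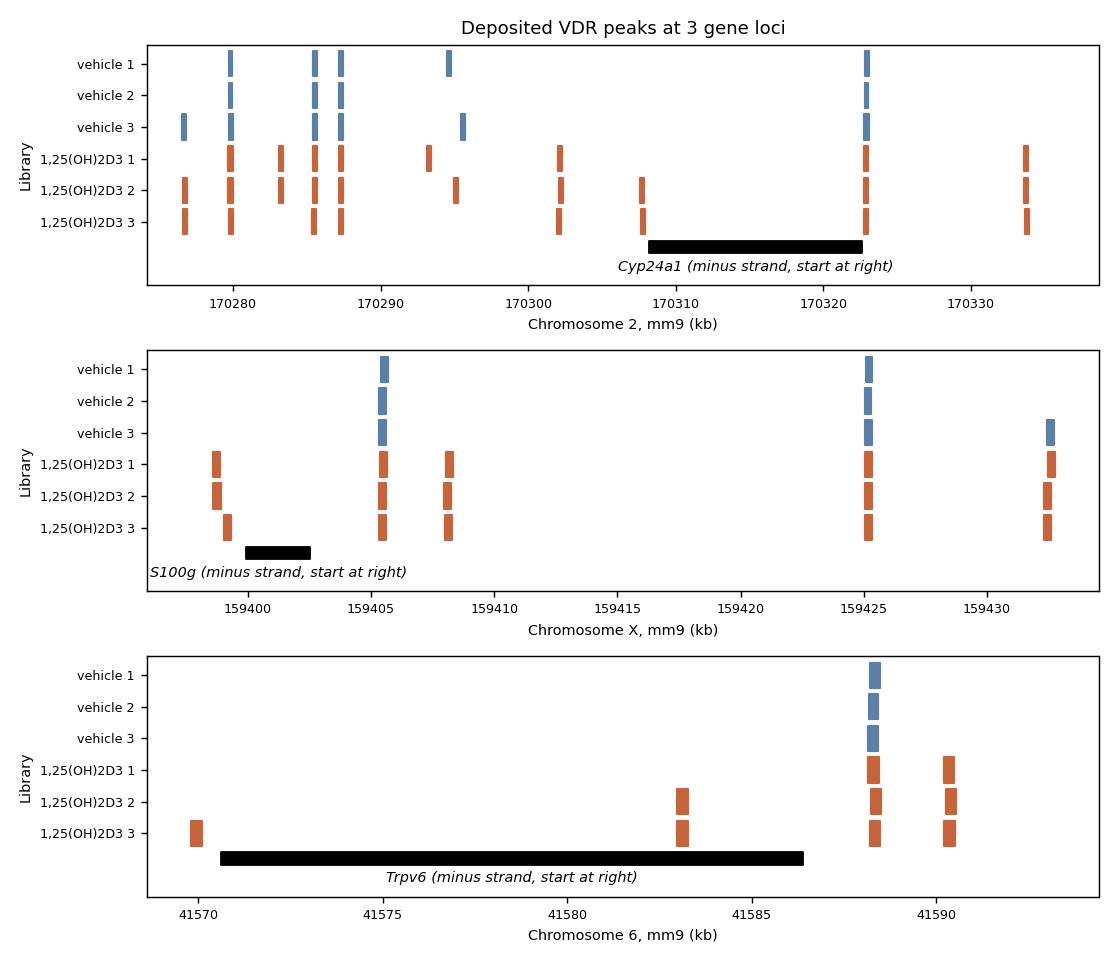
Deposited VDR peaks (bars) in each library at Cyp24a1, S100g and Trpv6, with the gene body in black and the mm9 position in kb on the horizontal axis. Blue bars are vehicle and orange bars 1,25(OH)2D3 libraries. The promoter of Cyp24a1 has a peak in all 6 libraries, and the region 3.97 kb upstream of Trpv6 has one in the 3 1,25(OH)2D3 libraries only.

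Libraries from hormone-treated mice resembled one another more than vehicle libraries did. The Jaccard index, the number of regions shared by 2 libraries divided by the number in either, was 0.490 ± 0.052 (SD, 3 pairs) among 1,25(OH)2D3 libraries, 0.192 ± 0.105 (SD, 3 pairs) among vehicle libraries and 0.237 ± 0.058 (SD, 9 pairs) across groups. Lists of unequal length limit this index. With lists of equal length it was 0.682 ± 0.034 among 1,25(OH)2D3 libraries, 0.351 ± 0.071 among vehicle libraries and 0.410 ± 0.077 across groups. Without vehicle replicate 3, the remaining vehicle pair had 0.311 and the 6 pairs across groups 0.257 ± 0.063 (all peaks). With lists of equal length this order was reversed, at 0.312 for the vehicle pair and 0.370 ± 0.061 (SD) across groups. Over all peaks and libraries, the mean within groups was 0.104 above the mean between groups (exact permutation p = 0.1, the smallest possible). The difference was 0.188 without vehicle replicate 3, 0.192 without vehicle replicate 2, and 0.0429, 0.0228 and 0.0237 without 1,25(OH)2D3 replicates 1, 2 and 3.

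**Figure D3:**
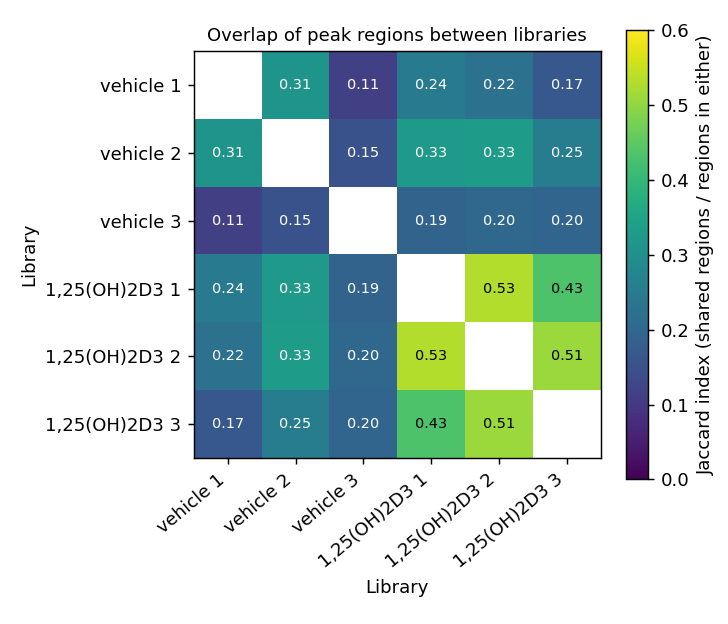
Jaccard index of regions (shared divided by those in either) for each pair of the 6 libraries, as colour and number. Pairs of 1,25(OH)2D3 libraries average 0.490 and pairs of vehicle libraries 0.192.

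VDR regions lay near genes of 7 of the 15 fixed lists more often than near matched genes, among them enterocyte function and phosphate and metal transport, while calcium transport did not pass. All 20 enterocyte genes had a region in at least 2 of 3 1,25(OH)2D3 libraries within 50 kb, against 77.2% of matched genes (adjusted permutation p = 0.0165). The same adjusted p was found for phosphate and metal transport (19 of 19 genes, matched 73.4%), bile acid and xenobiotic handling (19 of 19, matched 75.9%) and intestinal transcription factors (13 of 13, matched 66.7%). Tight junction and cell adhesion genes had regions at 10 of 10 (matched 68.9%, adjusted permutation p = 0.0296), a call lost with 1 gene per cluster of neighbours (9 of 9, adjusted permutation p = 0.0553). Cell cycle and growth control genes had them at 10 of 11 (matched 53.1%, adjusted permutation p = 0.0192). Stem cell and Wnt genes had them at 10 of 10 (matched 64.0%, adjusted permutation p = 0.0192), but this list passed in only 3 of 13 other settings. It had 9 of 10 without 1,25(OH)2D3 replicate 2 (adjusted permutation p = 0.0699) and with regions in all 3 1,25(OH)2D3 libraries (0.051), and 3.8 regions per gene against 2.93 for matched genes (0.346).

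The values of single genes stand beside the higher number of regions with hormone over all genes, and vehicle replicate 3 held more peaks than both other vehicle libraries at 53 of 76 named list members. Mean peak number was higher with hormone at 68 and lower at 6 of these 76, and higher at 73 and lower at 0 without vehicle replicate 3, a count made after the values were seen. Outside the calcium and vitamin D lists, ties in naming members were broken by the number of regions with hormone. That choice favours genes with more peaks with hormone, so the direction count is partly fixed by it. Among the enterocyte genes, Slc15a1, the peptide transporter, had 9.67 ± 5.03 peaks per library with vehicle and 15 ± 2.65 with hormone, and Fabp2, a fatty acid binding protein, 3.67 ± 2.08 and 10.7 ± 3.21 (SD, n = 3, here and in the values that follow). Slc5a1, the sodium-glucose transporter, had 7 ± 1 and 10.3 ± 2.08, and Alpi, intestinal alkaline phosphatase, 5 ± 2.65 and 9 ± 1. In the metal list, Slc34a2, a phosphate transporter, had 9.67 ± 1.15 with vehicle and 16 ± 3.61 with hormone, and Slc30a10 had 10.7 ± 4.04 and 14.3 ± 0.58. The zinc transporters Slc39a14 and Slc39a4 both averaged 5 with vehicle and 11.3 with hormone. Of the bile acid and xenobiotic genes, Abcg2, an efflux pump, had 8.67 ± 3.79 and 11.7 ± 1.53, and Nr1h4, the bile acid receptor, 6.33 ± 2.08 and 10.7 ± 2.52. Abcc2 and Abcc4, efflux pumps as well, averaged 9.67 and 4 with vehicle and 11.7 and 8.33 with hormone.

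Tcf7l2, the main Wnt effector of the crypt, had 10 ± 1 peaks with vehicle and 17.3 ± 4.16 with hormone, 4 of its 15 regions being hormone-only. Gata4, which specifies proximal intestine, had 7 ± 4.36 and 14.7 ± 0.58, and Creb3l3 averaged 4 with vehicle and 8.67 with hormone. Cldn3, a sealing claudin, had 4 ± 2 and 11 ± 2, and Cdh1, E-cadherin, 5.67 ± 3.21 and 12 ± 3.46. Ocln, another tight junction protein, averaged 6.33 with vehicle and 9.33 with hormone. Prom1, a stem cell surface protein, had 4 ± 2.65 and 10.3 ± 1.15, and Cd44 had 1, 1 and 8 in vehicle replicates 1, 2 and 3 and 3 in each 1,25(OH)2D3 library. Cdkn1a, an inhibitor of the cell cycle, had 3.33 ± 1.15 and 7.67 ± 0.58, and Fos, an immediate early gene, 7 ± 2.65 and 9.67 ± 2.31.

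Calcium transport genes had regions at 12 of 14 (matched 69.7%, adjusted permutation p = 0.246), without Slc8a1 and Cldn12. Vitamin D genes had them at 8 of 10 (matched 73.7%, adjusted permutation p = 0.649), without Cyp2r1 and Rxrg. By the number of regions per gene, a measure added after the data were seen, calcium genes averaged 4.57 against 2.82 for matched genes (adjusted permutation p = 0.0497), and vitamin D genes 4.70 against 2.92 (0.0682). Within the calcium list, Cldn2 and Cldn15, pore-forming claudins, averaged 8 and 10.7 peaks with hormone and 3.33 and 6 with vehicle. The lists of other cell types did not pass. Peaks near their members were also counted: per library, Clca3 of goblet cells had 2.33 ± 1.15 with vehicle and 6.67 ± 1.53 with hormone, Cck of enteroendocrine cells 5 ± 1.73 and 7 ± 2, the endothelial gene Pecam1 6.33 ± 4.04 and 10.3 ± 2.89, and the neuronal gene Grin1 2 ± 1.73 and 7 ± 1.73. Regions were near 5 of 7 goblet cell (adjusted permutation p = 0.835), 3 of 5 Paneth cell (0.664), 9 of 11 enteroendocrine and tuft cell (0.303), 10 of 12 immune (0.649), 6 of 11 stromal (0.835) and 9 of 12 neuronal genes (0.649). For the goblet cell, Paneth cell, immune and vitamin D lists, the central range of matched lists already reached 100%. Their shares had little room to pass, so this test decides nothing for these lists. The number of regions per gene has no such ceiling. By it, goblet cell genes averaged 2 against 3.03 for matched genes, Paneth cell genes 1.4 against 1.99 and immune genes 2.67 against 3.09.

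The lists passed against a high background, since 70.2% of all protein-coding genes had such a region, and 0 lists passed with a window of 100 kb. With regions in at least 2 of 3 vehicle libraries 6 lists passed, and the difference between the groups was not tested per list. With hormone-only regions 2 lists passed, tight junction and cell adhesion (9 of 10 genes, matched 33.0%, adjusted permutation p = 0.0015) and intestinal transcription factors (9 of 13, matched 30.4%, 0.021), while calcium transport had 9 of 14 (matched 32.4%, 0.051), bile acid and xenobiotic handling 12 of 19 (matched 36.4%, 0.051) and the neuronal list 7 of 12 (matched 34.1%, 0.179).

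**Figure D4:**
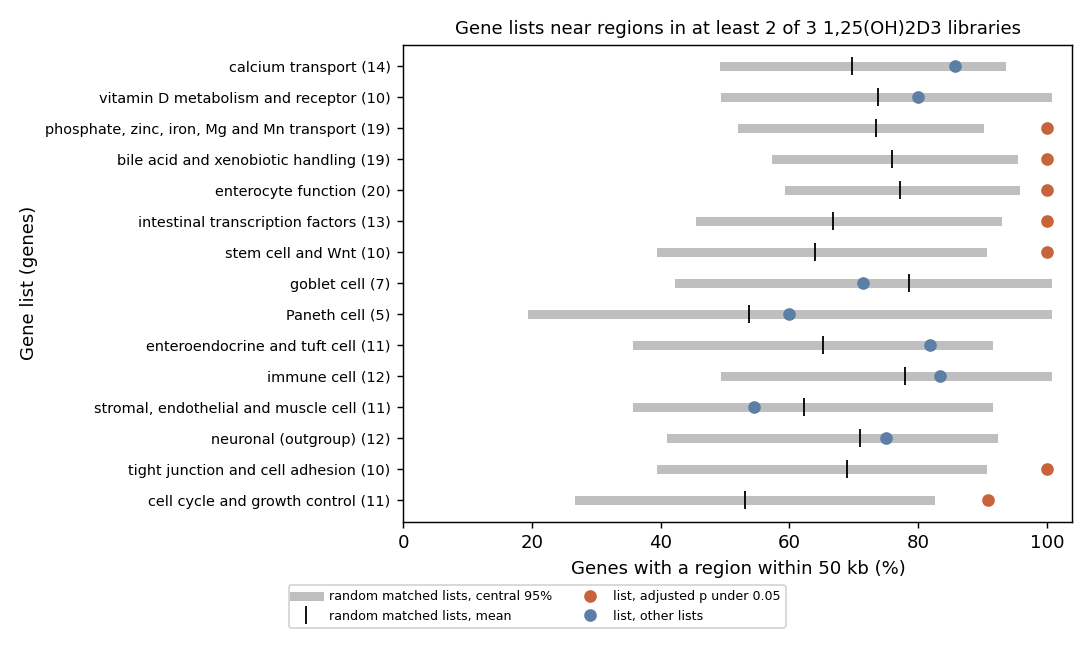
Percent of genes of each fixed list with a VDR region within 50 kb (points; number of genes in brackets), with the mean (tick) and central 95% (grey bar) of 10000 random matched lists. The 7 lists in orange passed the threshold after adjustment.

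VDR peaks were concentrated at promoters in both groups. Peaks within 1 kb of a transcription start made up 16.3% ± 0.98 (SD, n = 3) of the lists with hormone and 12.4% ± 4.21 with vehicle, against 4.12% of random positions. The difference of 3.82 points was within the spread (exact permutation p = 0.2, adjusted 0.4 over the 4 location classes). Introns held 41.9% of peaks in both groups (random 35.8%), exons 2.85% with hormone and 2.71% with vehicle, and the space between genes 39.0% and 42.9% (random 57.6%; exact permutation p = 0.1, adjusted 0.4). Hormone-only regions were near a transcription start in 20.1% of cases and regions in all 6 libraries in 13.8%. With lists of equal length the promoter difference was 3.97 points, all 3 1,25(OH)2D3 libraries lying above all 3 vehicle libraries (exact permutation p = 0.1, the smallest possible). The shares were then 15.3%, 17.6% and 21.0% in vehicle replicates 1, 2 and 3 and 21.7%, 21.6% and 22.5% in those with hormone. This setting keeps all of vehicle replicate 1 but only the first part of the other lists. Over whole lists the promoter difference was 1.40 points without vehicle replicate 3 and 1.93 points among the shallow libraries. The whole list of vehicle replicate 3 had a share of 7.61%, against 15.2% in the deep 1,25(OH)2D3 library.

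The VDR element DR3 was more frequent in both shared and hormone-only regions than in windows 5 kb away. With at most 1 mismatch it was found in 28.1% of regions in all 6 libraries (95% Wilson interval 26.8 to 29.5) and in 20.6% of hormone-only regions (19.4 to 21.7), against 4.81% and 4.35% of windows 5 kb away. Among the 26 vehicle-only regions it was in 1 (3.85%, interval 0.682 to 18.9). Per library and with at most 2 mismatches, DR3 was within 100 bp of 58.4% ± 2.38 (SD, n = 3) of peaks with hormone and 51.7% ± 9.96 with vehicle, against 35.2% at shifted windows. At this setting the other spacings were above shifted windows too, DR1 being as frequent (58.2% with hormone and 54.0% with vehicle, shifted 38.9%). With at most 1 mismatch DR1 was in 18.0% of regions in all 6 libraries (shifted 5.59%), below DR3. The DR3 difference of 6.66 points was within the spread (exact permutation p = 0.4, adjusted 0.955 over 15 motifs). With lists of equal length it was 7.69 points, and 4 points with at most 1 mismatch. In both, all 3 1,25(OH)2D3 libraries lay above all 3 vehicle libraries (exact permutation p = 0.1, the smallest possible). This setting keeps all of vehicle replicate 1 but only the first part of the other lists, where DR3 was most frequent. Over whole lists with at most 1 mismatch the difference was 2.95 points (exact permutation p = 0.5), and 0.522 points among the shallow libraries. Vehicle replicate 1 then had the highest share of any library, at 19.8%. With at most 2 mismatches and whole lists, the difference was 1.23 points without vehicle replicate 3 and 11 points without vehicle replicate 1. Among the shallow libraries it was 2.23 points, and the deep libraries had 56.4% with hormone and 40.8% with vehicle.

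Motifs of the GATA, AP1, KLF, CDX and HNF4 families were also more frequent at VDR regions than at shifted windows. The other 3 motifs that are not direct repeats were above shifted windows too, but each was in at most 0.990% of regions in all 6 libraries. In regions in all 6 libraries the GATA motif was found in 22.8% (8.52% at shifted windows), AP1 in 10.4% (3.73%), KLF in 8.84% (3.91%), CDX in 7.16% (2.76%) and HNF4 in 5.98% (0.644%). In hormone-only regions the shares were 16.2% for GATA, 8.58% for AP1, 5.23% for CDX and 4.31% for HNF4, each lower than in all 6, and 9.64% for KLF, which was higher. Per library, GATA was found in 18.5% of peaks with hormone and 18.4% with vehicle, and HNF4 in 4.47% and 4.27% (exact permutation p = 1 for both, n = 3). DR3 was most frequent at the head of every list, in 36.4%, 30.3% and 19.6% of the first 10% of the lists of vehicle replicates 1, 2 and 3 (at most 1 mismatch). For 1,25(OH)2D3 replicates 1, 2 and 3 the shares of the first 10% were 33.9%, 28.8% and 27.2%. In the last 10% of the list of vehicle replicate 3 it was in 4.65%.

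**Figure D5:**
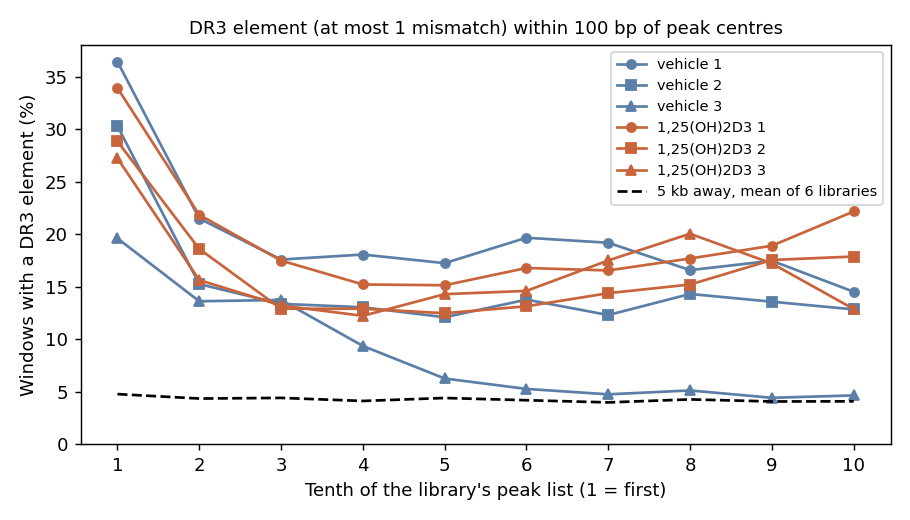
Percent of windows with a DR3 element (at most 1 mismatch, within 100 bp of the peak centre) along each library's list in 10 equal parts, with windows 5 kb away as the dashed line. Blue lines are vehicle and orange lines 1,25(OH)2D3 libraries. Vehicle replicate 3 falls to the level of the shifted windows in the lower part of its list, at 4.65% in the last part.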

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

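The tests with equal-length lists, with the first 50% of each list, with the 4 shallow libraries, with treated-only regions and with the number of regions or 1 gene per cluster, the leave-one-out tests of location, motif and gene lists, and the replicate block of location were chosen only after the data were seen. Hormone-only regions outnumbered vehicle-only regions in every setting of these tests, but not between the 2 deep libraries alone (27063 against 33766). The counts were 762 and 177 with lists of equal length, 2150 and 14 with the first 50% of each list, 8600 and 206 with the 4 shallow libraries, and 10733 and 410 with presence in at least 2 of 3 libraries. Leaving out 1 library gave 5166 to 8297 hormone-only and 35 to 220 vehicle-only regions, where the higher counts follow from fewer libraries having to lack or hold a peak. Regions in all 6 libraries numbered 2804 with lists of equal length, 2894 with the first 50%, 9547 with at least 2 of 3 in each group, and 4371 to 6935 with 1 library left out. The number of lists near regions was 0 within 100 kb, where all 7 lists had raised shares but no adjusted p under the threshold (the lowest was 0.057), 4 with regions in all 6 libraries and 2 with hormone-only regions. In the other 10 settings 6 or 7 lists passed, but not always the same ones. Over all 13 settings the stem cell and Wnt list passed in 3 (adjusted p 0.0099 to 0.886), cell cycle and growth control in 10, and each of the other 5 called lists in 11. The stem cell and Wnt list did not pass within 10 kb (0.0673), with regions in all 3 1,25(OH)2D3 libraries (0.051), with vehicle regions (0.391), with lists of equal length (0.171), without 1,25(OH)2D3 replicate 2 (0.0699) or by the number of regions per gene (0.346, and 0.315 with 1 gene per cluster), and calcium transport passed only by that number (0.0497 and 0.0495). With 1 gene per cluster the tight junction list did not pass (0.0553).

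Peak number, overlap, promoter share and DR3 share had no alternative with another direction, apart from the higher peak number of vehicle in the deep pair alone, but 3 against 3 libraries cannot pass the threshold, so this says nothing of their stability. Over single libraries left out, the log2 difference in peak number went from 0.25 (vehicle replicate 1) to 1.48 (vehicle replicate 3), the overlap difference from 0.0228 (1,25(OH)2D3 replicate 2) to 0.192 (vehicle replicate 2), the promoter difference from 1.40 (vehicle replicate 3) to 5.24 points (vehicle replicate 1) and the DR3 difference from 1.23 (vehicle replicate 3) to 11 points (vehicle replicate 1). Whether replicate numbers pair the libraries was not settled, so block results stand here only. Same-number correlations across regions were 0.0025, 0.0713 and 0.10 for replicates 1, 2 and 3. Pairs with unlike numbers went from -0.0913 to 0.0284. In the replicate block the peak number difference of 0.79 had an exact sign-flip p of 0.5. The promoter and DR3 differences of 3.82 and 6.66 points had an exact sign-flip p of 0.25 (the smallest possible). Same-numbered pairs overlapped by 0.0299 more than other pairs across groups (exact permutation p = 0.167, the smallest possible). Without tag counts per peak, depth limits every statement on absence: a region missing from a shallow list was not detected there, which does not show it unoccupied.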

Other observations

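The tests of motifs at regions with and without DR3, of genes with many regions, of strong regions missing from 1 library, of the background, VDR-site and depth explanations for vehicle replicate 3 and of short vehicle lists were chosen only after the result was seen, as was the pattern in the middle of the lists. The comparison of the hormone-only count with other splits of the libraries was fixed in advance, but the rule for reading it was set afterwards.

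Several genes outside the fixed lists had many VDR regions within 50 kb, counted in at least 2 of 3 1,25(OH)2D3 libraries and, in brackets, in at least 2 of 3 vehicle libraries. Myo5b, a motor of apical membrane traffic, had 29 (4), Shroom3, a regulator of apical constriction, 29 (8), and Chn2 27 (8). Longer genes with as many were Arhgap26, with 33 (19), and Arfip1, with 32 (10). Among genes shorter than 50 kb, Me2, a mitochondrial malic enzyme, had 18 (9), Mogat2, an enzyme of dietary fat absorption, 15 (7), Stat6, an effector of interleukin signalling, 15 (4), and Ezr, which anchors microvilli, 14 (8). Hormone-only regions were most numerous at Rap1gap2 (8 of its 15 regions, with 1 in at least 2 of 3 vehicle libraries), at Arfip1, Shroom3 and Prkag2 (7 each), and at Mecom, Irak2, Atxn2, Sema4a and Anxa4 (6 each). Anxa4 had 0 regions in all 6 libraries. These genes were chosen by their values, and Gm20388 and Fgfr2, with 27 and 11 hormone-only regions, were set aside because the annotation gives them lengths of 4434882 and 3009069 bp. The short genes named are a selection: Manbal, with 16 (8), 2410017I17Rik, with 15 (7), and others with 14 are not among them. Counts were not scaled to length. Arfip1, at 1391424 bp, was kept with 2.15 regions per 100 kb of its window, against 3.09 at Gm20388 and 1.99 at Fgfr2.

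Regions with no close match to the VDR element carried more GATA and CDX motifs, elements of intestinal transcription factors, than regions with one. In this comparison, regions without a DR3 held none with at most 2 mismatches, and regions with a DR3 held one of at most 1 mismatch. Regions whose closest DR3 had 2 mismatches were in neither set. The sets were not matched for GC content, so whether it accounts for the differences was not tested. More than 1 kb from transcription starts, GATA was in 24.8% (95% Wilson interval 23.9 to 25.7) of 8927 regions without a DR3. It was in 18.7% (17.6 to 19.9) of 4556 regions with one. CDX was in 8.26% (7.70 to 8.84) and 5.22% (4.61 to 5.91), and HNF4 in 5.81% and 4.83%. AP1 was in 11.4% and 11.5%, KLF in 8.00% and 8.27%, and ETS in 0.571% and 0.549%. A total of 6 motifs were looked at in this way. Over regions at any distance from a start 8 were looked at, and DR1, a repeat of the same element with another spacer, was in 17.0% with a DR3 and 13.5% without, and CTCF in 0.778% and 0.517%.

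Vehicle replicate 3 had 32166 regions found in no other library. Their DR3 share was 0.211 percentage points above that of windows 5 kb away, which is consistent with peaks called in background reads. For these private regions, the values argue against DR3 or promoter sites of the receptor held without added hormone as their main source. The share near transcription starts was -0.114 points relative to random positions, and the DR3 share was near that of shifted windows. Sites also found in another library were left out by definition, so nothing is said of them. The private windows held 39.4% GC, against 41.3% when shifted, and GC content was not matched. The regions private to the similarly deep 1,25(OH)2D3 replicate 3 had a DR3 share 8.68 points above shifted windows, so depth does not always give private regions without DR3. That library had 18.96% of its tags in peaks, against 8.10% in vehicle replicate 3. It therefore cannot decide what depth does in a less enriched library. Sites without both DR3 and promoters, depth in a less enriched library and a difference in sequencing run stay open and were not tested.

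For the 4687 hormone-only regions, the highest count in any other split of the 6 libraries was 1092, and 1 of the 10 splits reached the real value, too few splits to give a share under 0.05. With lists of equal length the count was 762 and the highest other split 151, which argues against short vehicle lists as the whole cause. Weaker immunoprecipitation in the vehicle libraries stays open, because the lower share of tags in peaks and the shorter fragments go with the vehicle group, so library quality cannot be told apart from treatment. Under that explanation fewer than 1% of hormone-only regions should lie in the first 10% of all 3 lists, and 0.875% did (95% Wilson interval 0.645 to 1.18%, which includes the bound; the interval was asked for only after the value was seen). Hormone-dependent recruitment of the receptor stays open as well, and a test of it needs tag counts per region.

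In the 1,25(OH)2D3 lists DR3 was rarer in parts 3 to 5 than in parts 7 and 8 of 10 equal parts, a difference of -2.91 percentage points as the mean of 3 libraries. Without peaks within 1 kb of transcription starts the difference was -1.89 points (-0.422 in the library closest to 0), and within windows of 44 to 50% GC it was -2.86 points (-0.784). Without 1,25(OH)2D3 replicate 3 these 3 values were -1.60, -0.770 and -1.12. Promoter peaks may account for part of it, and neither test decides for promoter peaks or for GC content, given the spread between the libraries. The vehicle lists differed from one another, with -0.251, -0.472 and 4.85 points for replicates 1, 2 and 3 by the same measure over all peaks. No biological explanation was tested.

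Of 22 regions in 2 of 3 1,25(OH)2D3 libraries with a mean percentile of at least 95, 18 (81.8%) had a peak of the missing library within 5 kb. Regions in all 3 with such a percentile lack no library, so 1 of the 3 was drawn at random for each. A further peak of that library, apart from the region's own, lay within 5 kb at 440 of 1448 (30.4%). These shares rest on different counting rules and are not the same measure. The region 39.4 kb from the start of Cyp24a1 is among the 22. Chromosome Y held 25 peaks in vehicle replicate 3, 18 in 1,25(OH)2D3 replicate 3 and 0 in the other 4 libraries. Chromosome X held 1.78% to 2.20% of the peaks of each library, with 0.494% to 0.672% in the first 10% of each list.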
